A study of Arabidopsis thaliana with 9 samples.

How the data were processed

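The samples were 9 microarrays of Arabidopsis thaliana, 3 for each of 3 groups. Per the labels and the series' design text, wild-type seedlings 4 d old were moved to medium with 45 µM FPX, and total RNA of whole seedlings was taken after 0, 2 and 8 d. RNA was isolated with a spin-column kit and labelled by the standard Affymetrix protocol. The labels name both Cy3 and biotinylated cRNA, and which dye was read is not given in the sources used here. The series' design text says that the 0 d arrays were re-analysed from raw data shared with another series, so their deposited values differ from those given there. Arrays of seedlings on auxin and cytokinin, which the labels mention, were not analysed here.

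The authors deposited 1 table of array intensity with a value for each probe set on each of the 9 arrays. Per the submitters' processing notes, the values were made with MAS5, whose version is not given in the sources used here. The deposited intensity values were all positive and on a linear scale, and were not centred for each probe set. The step that brought the arrays to a common level is not given in the sources used here. The 75th percentile of the signal lay between 1046 and 1103 on each array. No background level or detection call was used here, so the signal above background is unknown, and the number of arrays limits the precision. Every column of the table was matched to a sample by its name.

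The table held 11249 probe sets, of which 21 were Affymetrix controls and 11228 were tested. The rule by which the probe sets were chosen is not given in the sources used here. A comparison of the 3 groups on log2 values, probe set by probe set, passed a bound of 0.04 for 11202 of the 11228 (99.77%). The bins on both sides of that bound held 294 probe sets from 0.03 to 0.04 and 4 from 0.04 to 0.05. The table therefore holds probe sets selected for differing between the groups. Counts of changed probe sets, their split into rises and falls, and the number of measured members of each gene list depend on that selection, and are not shares of the genome.

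Probe sets were named through the platform annotation, with symbols updated by gene identifier from the RefSeq gene table. A probe set of 1 gene was found in 5981 cases, of which 5962 matched by identifier and 19 kept the platform's symbol. Several genes were given for 222 probe sets, and 5025 were not listed and stayed unnamed here. Of the 5981, 909 had a symbol of their own and 5072 had a locus code alone. No probe set with several genes was named.

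Values were tested as log2(signal + 16), so fold changes are on that scale and understate the change of dim probe sets. No dim probe set was left out. A model with 1 mean per group was fitted over the 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with default settings), with 6 residual and 5.24 prior degrees of freedom. The contrasts were 2 d against 0 d, 8 d against 0 d and 8 d against 2 d, each with a two-sided moderated test, and a moderated F test covered both treated times. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The contrast of 8 d with 2 d is also the test of the difference between the effects at both times. The labels number the arrays of a group without saying that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Tables were read with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and plots were drawn with matplotlib 3.10.9.

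Before the data were examined, 26 gene lists and 9 lists of tissue or cell type markers were fixed from general knowledge. Of these, 10 had 3 or more measured genes and 7 had none. Each list was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, and p-values were adjusted over the 10 lists and 3 contrasts (30 tests). Another 27 groups of genes were assembled from the named genes of the table before fold changes were examined, and 1 group, the transcripts encoded in mitochondria, after its values had been seen. These 28 groups formed a family of 84 tests.

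The rule for named genes was fixed before the data were examined. It took, for each contrast, the 10 largest rises and 10 largest falls among probe sets that passed the threshold, whose groups did not overlap, that belonged to 1 gene with a symbol and were not of a kind shared by several genes, and whose mean in the higher group was above the median of all probe sets. From each list it took up to 4 members that passed in a contrast against 0 d, or the 2 largest changes where none passed, and the reference genes. Other genes named in the text were chosen after their values were seen.

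The fit was tested on simulated data made from the 0 d means and the fitted spread of each probe set over 11228 probe sets. Of 100 probe sets changed 2-fold, 99, 100 and 100 were recovered in the contrasts of 2 d with 0 d, 8 d with 0 d and 8 d with 2 d. Of 100 changed 1.5-fold, 83, 82 and 91 were recovered, and 14, 8 and 15 unchanged probe sets were called. Far fewer probe sets were changed here than were called in the data, and the spread came from a table selected for group differences. These counts therefore do not give the recovery or false calls of the real fit.

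Alternatives set before the data were examined were quantile normalization, array medians set to 0, pseudocounts of 1 and 64, removal of the 2807 dimmest probe sets or of all but the 5614 brightest, a trended and robust prior, a fit of the compared groups alone, the replicate number as a block, an adjusted p under 0.01, a fold of at least 2, genes in place of probe sets, and leaving out each array in turn. Chosen after seeing the data were a scaling on the hybridization controls and an adjustment as for 2 times as many tests, which allows for probe sets that the table leaves out. Those controls were themselves selected for differing between the groups, so this scaling may be biased. No scaling on the poly(A) controls was run.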

Results

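Transcript levels were measured on Affymetrix arrays in wild-type Arabidopsis thaliana seedlings before and during treatment with the compound FPX. Seedlings 4 d old were moved to medium with 45 µM FPX, and whole seedlings were collected at 0, 2 and 8 d, with 3 arrays per group. The stated aim was to find genes affected by FPX and to set them beside auxin and cytokinin treatment, which was not analysed here. The treated seedlings were also 2 and 8 d older than those at 0 d, and untreated seedlings of those ages were not analysed here, so each contrast with 0 d holds treatment and age together. The 0 d arrays were shared with another series, and whether all 9 arrays were hybridized together is not given in the sources used here, so a batch difference is not separated from treatment in contrasts with 0 d either. Arrays of a group correlated at r = 0.987 to 0.991 over probe sets, against 0.881 to 0.893 between 0 d and 2 d, 0.832 to 0.856 between 2 d and 8 d, and 0.712 to 0.733 between 0 d and 8 d. These probe sets had been selected for differing between the groups, which by itself lowers the values between groups, so the gap is no test of group separation. The 100 brightest probe sets held 11.1 to 12.1% of the summed signal at 0 d, 10.1 to 10.3% at 2 d and 8.25 to 9.18% at 8 d. The hybridization controls in the table had a mean log2 change of −0.105 at 2 d and −0.247 at 8 d, and the poly(A) controls, which are added before labelling, −0.365 and −0.568.

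The table held probe sets selected for differing between the 3 groups. A one-way comparison of the 3 groups passed at 0.04 for 11202 of the 11228 tested probe sets. Counts and splits below therefore do not stand for the genome, and the lists hold only those members that were selected and could be named. The p-values measure only the spread between these samples.

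After 2 d on FPX, transcripts of auxin response and of mitosis were higher than before transfer, and transcripts of chlorophyll synthesis were lower. In the auxin response list 7 of 7 measured genes rose, with a median log2 change of 1.93, and in the list of the G2 and M phases of the cell cycle 6 of 6 rose, with a median of 1.45. In the chlorophyll synthesis list 7 of 7 fell, with a median of −0.73. These lists held 43, 37 and 26 names, and most members were not found by name in the selected table. Members that did not differ between the groups would be absent from it, so the selection favours such full counts. Over all 11228 probe sets 5005 rose and 3155 fell at 2 d. Of 15 expansins and xyloglucan hydrolases, which loosen and remodel the cell wall, 10 fell and 4 rose, with a median of −0.94. TBL36 (AT3G54260), of a family that acetylates wall polysaccharides, had the largest rise among the named genes, a log2 change of 3.79 ± 0.11 (SE, 13.8-fold, limma adjusted p = 1.55e-09). Its mean signal went from 178 ± 6.4 (SD, n = 3) to 2690.5 ± 451. Of the named genes CP1 (AT4G36880) had the largest fall, −4.25 ± 0.32 (SE, adjusted p = 7.45e-07 in limma), and its mean signal went from 1359 to 53.7. Over all tested probe sets the largest rise was 4.69 and the largest fall −4.25.

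In the auxin list at 2 d, GH3.3 (AT2G23170), an enzyme that conjugates auxin to amino acids, rose by 2.94 ± 0.13 (SE, limma adjusted p = 1.86e-08). The Aux/IAA repressor gene IAA30 (AT3G62100) rose by 2.57, the transcription factor gene LBD16 (AT2G42430), known from lateral root formation, by 1.94 and the homeodomain gene HAT2 (AT5G47370) by 1.93. Among G2 and M phase genes, TOPII (AT3G23890), which encodes topoisomerase II, rose by 2.70 ± 0.12, the centromeric histone gene HTR12 (AT1G01370) by 1.76, the Aurora kinase gene AUR2 (AT2G25880) by 1.58 and the spindle checkpoint gene BUB3.1 (AT3G19590) by 1.32. A wider group of 13 genes of auxin conjugation and response, which includes 6 of the list, was not called (7 rose and 2 fell, camera adjusted p = 0.24), with falls of YUC2 (−0.66) and IAGLU (−0.50). Both measured genes of the S phase list rose, PRL (AT4G02060), a subunit of the replicative helicase, by 1.58 and the DNA polymerase gene ICU2 (AT5G67100) by 1.32. Other large rises were those of the thaumatin-like gene ATLP-1 (2.64), 3xHMG-box2 (2.58), the glycosyl hydrolase gene GH9B13 (2.36), the sugar transporter gene SAG29, whose mean signal went from 141 to 762, and RBL (AT3G55510, 2.00).

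Among chlorophyll synthesis genes at 2 d, PORB (AT4G27440), a protochlorophyllide oxidoreductase, changed by −0.99 ± 0.11, the magnesium chelatase gene CHLI2 (AT5G45930) by −0.80, HEME1 by −0.75 and HEMB1 by −0.73. Of 8 genes of light harvesting and the photosystems 3 fell at 2 d (2 when adjusted over the list alone). They were the antenna protein genes LHCB4.3 (−2.71 ± 0.17), LHCB4.2 (−0.40, which did not pass after quantile normalization) and LHCB4.1 (−0.26, and 0.0024 after quantile normalization, with no pass without 0 d replicate 1). Of 4 Calvin cycle and photorespiration genes 1 fell, SBPASE (−0.42), and the 4 had a median of −0.16. In the wall list XTH18 changed by −2.83 ± 0.14, XTH16 by −2.43 and XTH33 by −2.05, while EXPB3 rose by 1.48. A wider group of 25 genes of wall remodelling, which includes these 15, had 11 rises and 12 falls and was not called (camera adjusted p = 0.344). Of 13 genes of xenobiotic detoxification 8 fell and 1 rose, with falls of AER (−1.57), an alkenal reductase, of the glycosyltransferase genes UGT73B5 (−1.40) and UGT73B1 (−1.07), and of the glutathione transferase gene GSTU26 (−1.24), and a rise of UGT72E1 (0.72). Of 6 genes of senescence and starvation 4 fell (5 when adjusted over the list alone) and 1 rose, with a rise of SAG29 and falls of the autophagy gene ATG8E (−1.04) and WRKY6 (−0.71). The methionine sulfoxide reductase genes MSRB9 (−3.79) and MSRB6 (−1.92), BGLU28 (−2.90), SUFE2 (−2.20), UGT76B1 (−2.17) and TCP15 (−1.88) were other large falls. Among tissue markers, the stomatal peptide gene STOMAGEN changed by −1.45, the root genes NAI2 and PYK10 by −0.55 and −0.31 (PYK10 did not pass after quantile normalization, at −0.04, or under the scaling on hybridization controls), and the seed oleosin gene OLEO3 by −0.58. Of the phloem genes CLE44 rose by 1.36 and CLE41 fell by 0.79, and SWEET11 also passed when adjusted over the list alone, as did the trichome gene SIM.

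With camera at the preset correlation, the adjusted p at 2 d was 3.74e-04 for auxin response, 0.00168 for chlorophyll synthesis, 0.0041 for G2 and M phase, 0.00539 for xenobiotic detoxification and 0.00981 for the wall list. It was 0.0328 for light harvesting. With an estimated correlation the adjusted p was 0.189 for the first 5 of these lists and 0.432 for light harvesting, and of the 14 calls made at the preset correlation over the 30 tests, 0 held. The list counts adjusted over the list alone were otherwise the same as those over all probe sets in these lists. In all, 8160 of 11228 probe sets changed, 5005 up and 3155 down (61.3% up), of which 1037 rose and 555 fell at least 2-fold. The median log2 change of all probe sets was 0.17. It was −0.01 with array medians set to 0, where the median was 1.75 for auxin response, 1.27 for G2 and M phase, −0.91 for chlorophyll synthesis and −1.12 for the wall list. The split became 3542 up and 4116 down (46.3% up) with array medians set to 0, and 3694 up and 3542 down (51.1% up) after quantile normalization, and 5630 up and 2400 down (70.1% up) under the scaling on hybridization controls. The light harvesting call ended after quantile normalization (adjusted p = 0.793, median 0.03) and without 0 d replicate 1 (0.0608), the Calvin cycle median turned to 0.05 after quantile normalization, and the wall call ended without the 2807 dimmest probe sets (0.101).

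**Figure D1:**
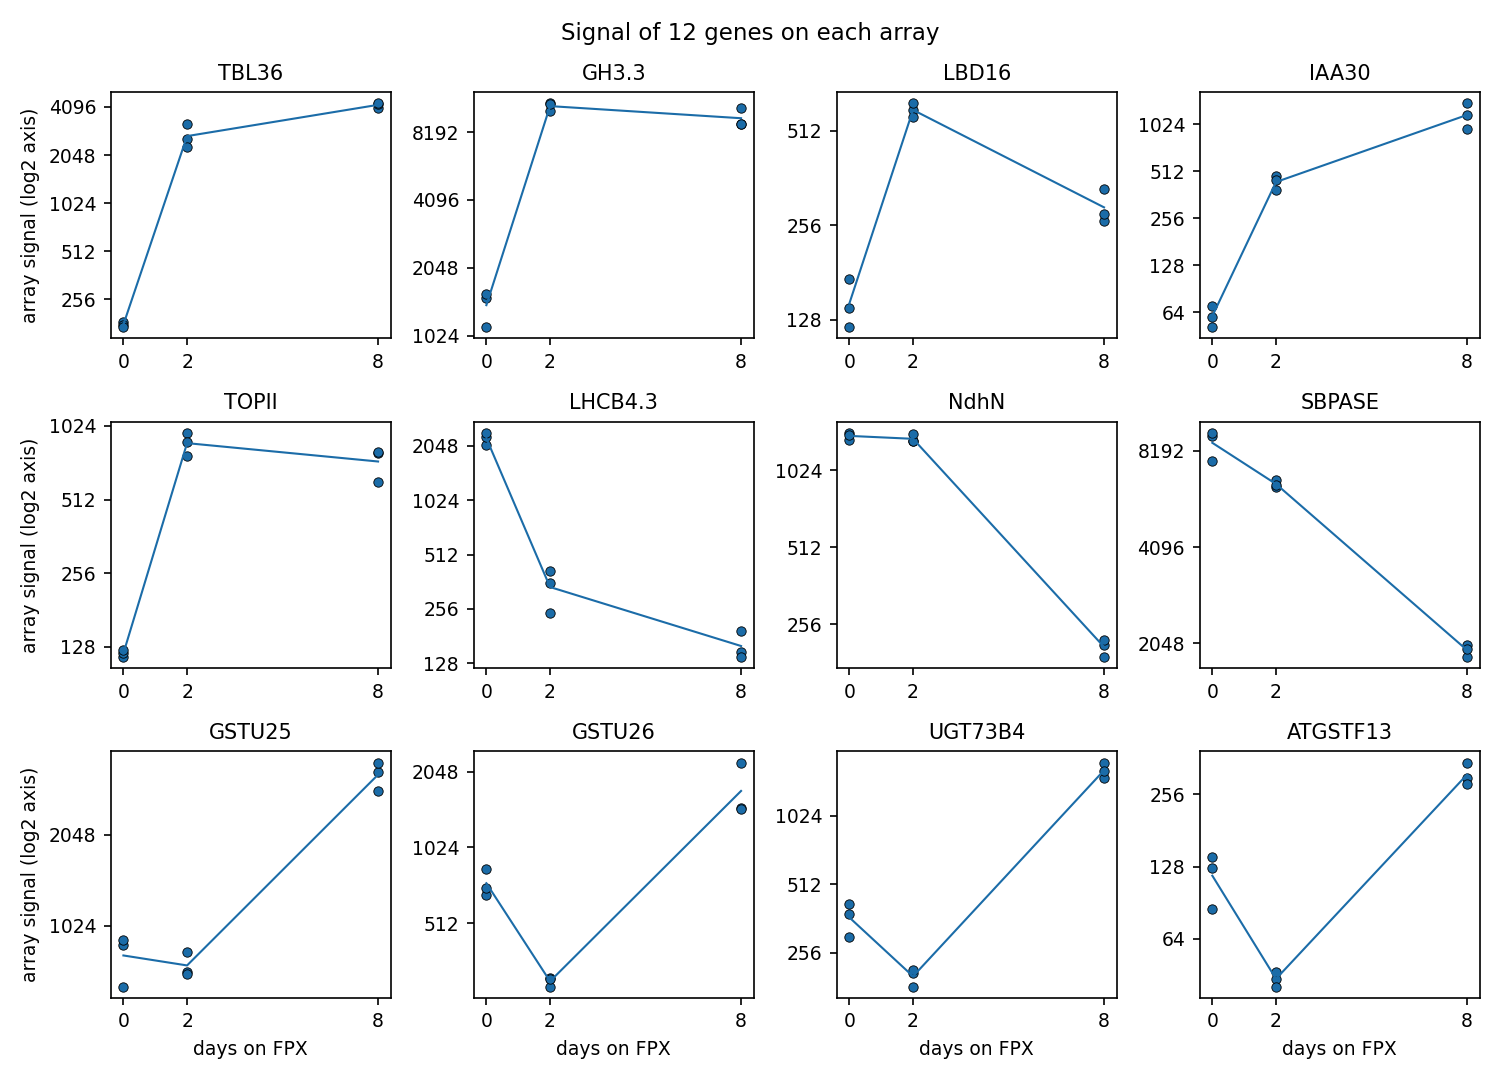
Array signal (log2 axis) of 12 genes against days on FPX (0, 2 and 8), with a point for each of the 3 arrays per group and a line through the group means; ATGSTF13 and the choice of the 12 were made after the values were seen. The auxin genes GH3.3, LBD16 and IAA30 were higher at both times than at 0 d, NdhN fell between 2 d and 8 d, and GSTU26 and UGT73B4 were lowest at 2 d.

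After 8 d on FPX, the measured photosynthesis transcripts of the fixed lists were lower than at 0 d, and those of auxin response and mitosis were still higher. In the chlorophyll synthesis list 7 of 7 genes fell (median −2.09), in the Calvin cycle and photorespiration list 4 of 4 (median −1.66), and in the light harvesting list 8 of 8 (median −1.21). In the auxin response list 7 of 7 rose (median 1.504), and in the G2 and M phase list 6 of 6 (median 1.25). The lists, in this order, held 26, 31, 48, 43 and 37 names, and most members were not found by name in the selected table. Members that did not differ between the groups would be absent from it. Over all 11228 probe sets 4058 fell and 6159 rose at 8 d. TBL36 again had the largest rise among the named genes, 4.45 ± 0.11 (SE, 21.9-fold, limma adjusted p = 2.05e-10), with a mean signal of 4223 ± 140 (SD, n = 3). Of the named genes MSRB6 (AT4G04840) had the largest fall, −4.33 ± 0.16 (SE, adjusted p = 8.49e-10 in limma), and its mean signal went from 1606 to 65.3. Over all tested probe sets the largest rise was 6.56 and the largest fall −5.46.

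Among photosynthesis genes at 8 d, CHLI2 changed by −2.50 ± 0.09 (SE, limma adjusted p = 8.57e-10), the methyltransferase gene of chlorophyll synthesis CHLM (AT4G25080) by −2.18, HEME2 by −2.14 and HEME1 by −2.09. The Calvin cycle genes SBPASE (AT3G55800) and PRK (AT1G32060) changed by −2.14 ± 0.09 and −1.64, the photorespiratory gene HPR (AT1G68010) by −1.67 and the rubisco activase gene RCA by −0.70, which did not pass after quantile normalization (−0.16). LHCB4.3 changed by −3.71 ± 0.17, PSBY by −1.72, LHCB4.2 by −1.48 and PSAN by −1.22. LrgB (AT1G32080), a plastid envelope transporter of photorespiration, changed by −3.27. In the auxin list IAA30 rose by 3.95 ± 0.14, GH3.3 by 2.75, HAT2 by 1.63 and WES1, not among the 4 largest rises, by 1.41. In the wider group of 13 auxin genes 9 rose and 4 fell (camera adjusted p = 0.305), with IAA18 at −1.09 and GH3.9 at −0.77. In the G2 and M phase list TOPII rose by 2.45, HTR12 by 1.39, BUB3.1 by 1.32 and AUR3 by 1.19, and in the S phase list ICU2 rose by 1.73, and PRL rose from a mean signal of 351 to 1013. Other large rises were those of the bZIP gene EEL (4.11), GH9B13 (3.78), ATLP-1 (3.14), the calmodulin-binding gene IQD26 (3.11), RRP41L (2.72), DI21 (2.55) and the peroxidase gene Prx37 (2.54).

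Of the 15 wall genes 10 fell and 5 rose at 8 d, with EXPA8 at −3.35 ± 0.12, XTH18 at −3.13, XTH16 at −3.03 and EXPA16 at −2.42. In the wider group of 25 wall genes 14 fell and 10 rose (camera adjusted p = 0.148). Of the 13 genes of xenobiotic detoxification 7 fell and 5 rose. UGT73B4 rose by 2.11 ± 0.12, GSTU25 by 1.98 and UGT72E1 by 1.62, and AER changed by −2.38. Of 3 genes of flavonoid synthesis 3 fell, UGT78D1 (−1.48), CHIL (−1.46) and UGT78D2 (−0.56). Of the 6 senescence genes 3 fell and 2 rose, with ATG8E at −1.75 and SAG29 at 1.33. Further large falls were those of CP1 (−4.20), MSRB9 (−3.64) and the dehydrin gene LTI30 (−2.77). Among tissue markers, STOMAGEN changed by −3.39 ± 0.15, the stomatal regulator gene FMA by −0.62 (−0.38 and no pass under the scaling on hybridization controls), the trichome gene SIM by −1.51 and PYK10 by −0.39 (0.15 after quantile normalization), while OLEO3 rose by 0.86. Of the phloem genes CLE44 rose by 1.65, and CLE41 and SWEET11 changed by −1.44 and −0.42, of which SWEET11 did not pass under the scaling on hybridization controls (−0.17).

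With camera at the preset correlation, the adjusted p at 8 d was 3.74e-04 for chlorophyll synthesis and for light harvesting, 0.00754 for the Calvin cycle list, 0.0123 for auxin response and 0.0347 for G2 and M phase. With an estimated correlation the adjusted p was 0.229 for G2 and M phase and 0.189 for the other 4. At the preset correlation the adjusted p did not pass for the wall list (0.0586), flavonoids (0.0807), xenobiotic detoxification (0.356) or senescence (0.495). In all, 10217 probe sets changed, 6159 up and 4058 down (60.3% up), of which 2407 rose and 1760 fell at least 2-fold. The split was 4934 up and 4609 down (51.7% up) with array medians set to 0, 5222 up and 4244 down (55.2% up) after quantile normalization, and 6640 up and 3141 down (67.9% up) under the scaling on hybridization controls. The median log2 change of all probe sets was 0.36. It was 0.11 with array medians set to 0, where the median was 1.25 for auxin response, −2.35 for chlorophyll synthesis, −1.91 for the Calvin cycle list and −1.46 for light harvesting. The G2 and M phase call ended without the 2807 dimmest probe sets (adjusted p = 0.0815), and the wall and flavonoid lists passed without FPX 2 d replicate 2 (0.0458 and 0.0498).

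**Figure D2:**
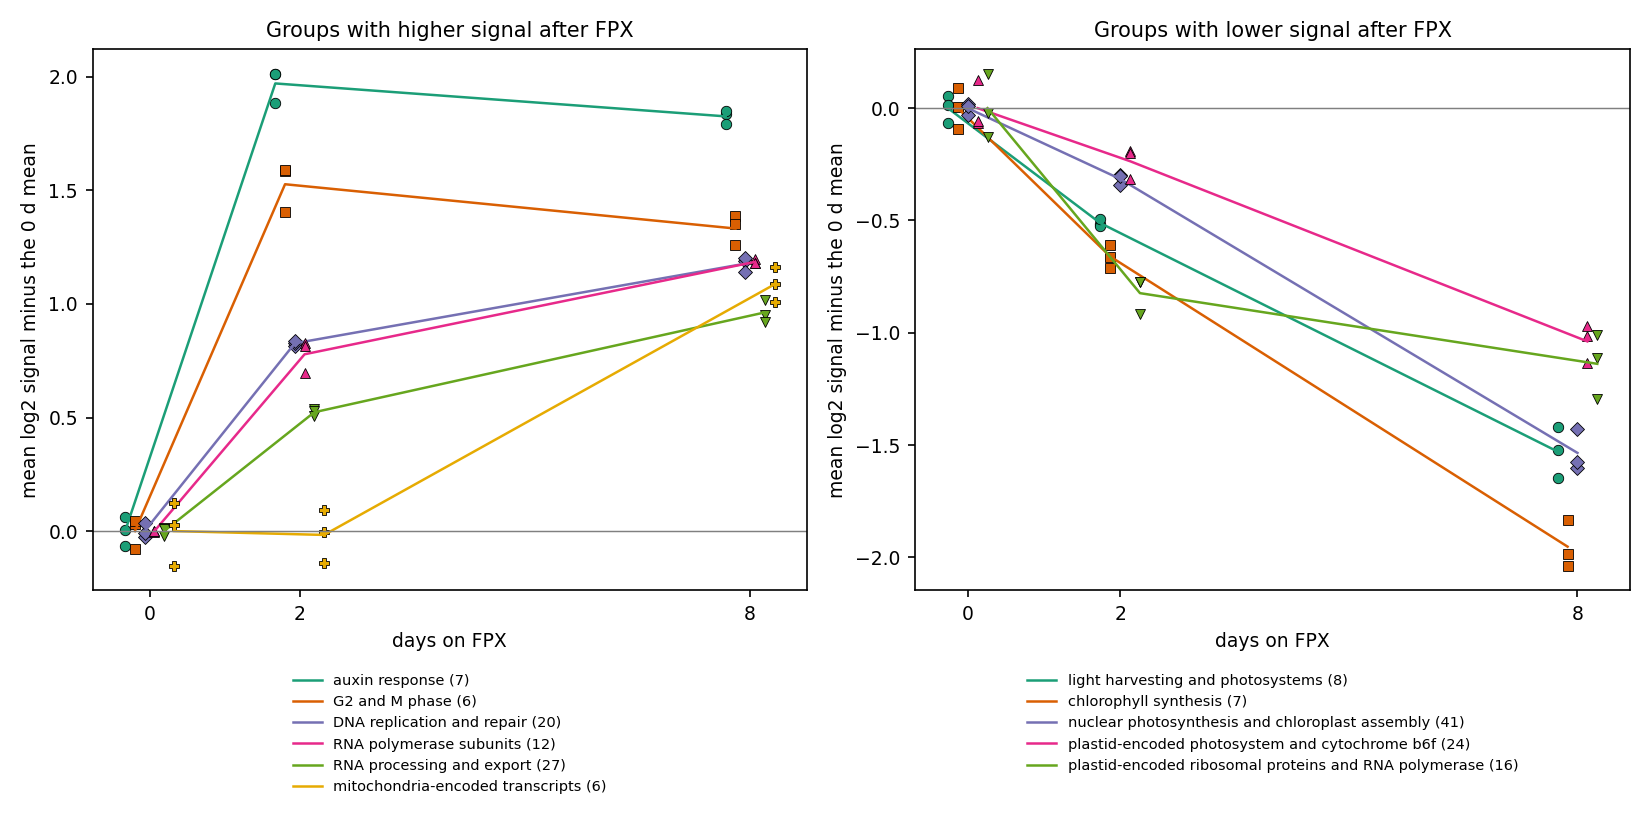
Mean log2 signal of each gene group minus its 0 d mean against days on FPX, with a point for each array, a line through the group means, and the number of genes in brackets; mitochondria-encoded transcripts were added after their values were seen. Auxin response and G2 and M phase genes were high by 2 d, with medians of 1.93 and 1.45, and light harvesting genes, whose 2 d median of −0.19 turned to 0.03 after quantile normalization, reached −1.21 at 8 d.

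Between 2 d and 8 d, photosynthesis transcripts of the fixed lists fell and the early auxin and mitosis rises did not grow as groups. In the light harvesting list 8 of 8 genes fell from 2 d to 8 d (median −0.97), in the Calvin cycle list 4 of 4 (median −1.53) and in the chlorophyll list 7 of 7 (median −1.34). In the auxin list 1 of 7 rose, IAA30 (1.38), and 4 fell, among them LBD16, from a mean signal of 596 to 292, and IAA29 (−0.74), while under the scaling on hybridization controls 2 rose and 3 fell. In the G2 and M phase list AUR3 rose (0.65) and AUR2 (−0.73), AUR1 (−0.47) and HTR12 (−0.37) fell. NdhN (AT5G58260), a subunit of the chloroplast NADH dehydrogenase-like complex, had the largest fall among the named genes, −2.62 ± 0.08 (SE, limma adjusted p = 2.31e-09), and its mean signal of 1395 at 0 d and 1358 at 2 d went to 208 at 8 d. Of the named genes sks15 (AT4G37160) had the largest rise, 3.76 ± 0.16 (SE, adjusted p = 1.09e-08 in limma). Over all tested probe sets the largest rise was 5.5 and the largest fall −4.35. List members named here for this contrast were chosen after their values were seen.

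Further falls from 2 d to 8 d were those of LrgB (−2.48), EXPA8 (−2.36), NdhL (−2.34), the sugar transporter gene SWEET2 (−2.11), the thylakoid ascorbate peroxidase gene TAPX (−2.09), HCF101 (−1.99), known from photosystem I assembly, the thioredoxin gene TRXF2 (−1.90), GSTU18 (−1.89) and CHLM (−1.89). Further rises were those of UGT73B4 (2.91), EEL (2.50), GSTU26 (2.42), the basic helix-loop-helix gene SPT (2.12), GSTU25 (2.07), CXE20 (1.92), DI21 (1.88), the chromatin remodelling gene BSH (1.67) and GER2 (1.60). With camera at the preset correlation, the adjusted p was 3.74e-04 for light harvesting and for chlorophyll synthesis and 0.00483 for the Calvin cycle list, and 0.189 for each of the 3 with an estimated correlation. At the preset correlation it was 0.327 for auxin response, 0.288 for G2 and M phase and 0.662 for xenobiotic detoxification, where 6 genes rose and 5 fell. It was 0.0939 for flavonoids, of which 3 of 3 fell, 0.356 for the wall list (3 rose, 6 fell) and 0.573 for senescence (2 rose, 2 fell). In all, 8534 probe sets changed, 4928 up and 3606 down (57.7% up), while of those that changed at least 2-fold 734 rose and 1255 fell. Over all changed probe sets the split ran from 51.9% up with array medians set to 0 to 66.4% up under the scaling on hybridization controls. The median log2 change of all probe sets was 0.15, and 0.078 with array medians set to 0, where the median was −1.04 for light harvesting, −1.61 for the Calvin cycle list and −1.42 for chlorophyll synthesis. The flavonoid list passed without FPX 2 d replicate 2 (0.0478).

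Over both times together, 11142 of 11228 probe sets passed the F test, a count that the selection of the table sets. TBL36, GH3.3, HAT2, TOPII and HTR12 rose at both times, and CP1, MSRB9, XTH18, CHLI2 and LHCB4.3 fell at both. Across probe sets, which are not independent replicates, the log2 changes at 2 d and 8 d had a Pearson r of 0.716 and a Spearman rho of 0.726. Unchanged groups that shared simulated 0 d arrays, with the fitted spread of each probe set, gave r = 0.5 over 100 simulations. The covariance was 0.609, against 0.00702 in the simulations, and 80% of probe sets had the same sign, against 66.7%. In both contrasts 4195 probe sets rose, where independent lists of those sizes would share 2745, and 2414 fell, where they would share 1140. The 3 arrays at 0 d were too few to split into parts of at least 2, so part of the excess in shared calls may come from the shared controls. Their spread accounts for little of the covariance, and a difference shared by all 3 of them was not simulated. The selection of the table and the upward shift of its medians were not simulated either, and may raise these values.

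**Figure D3:**
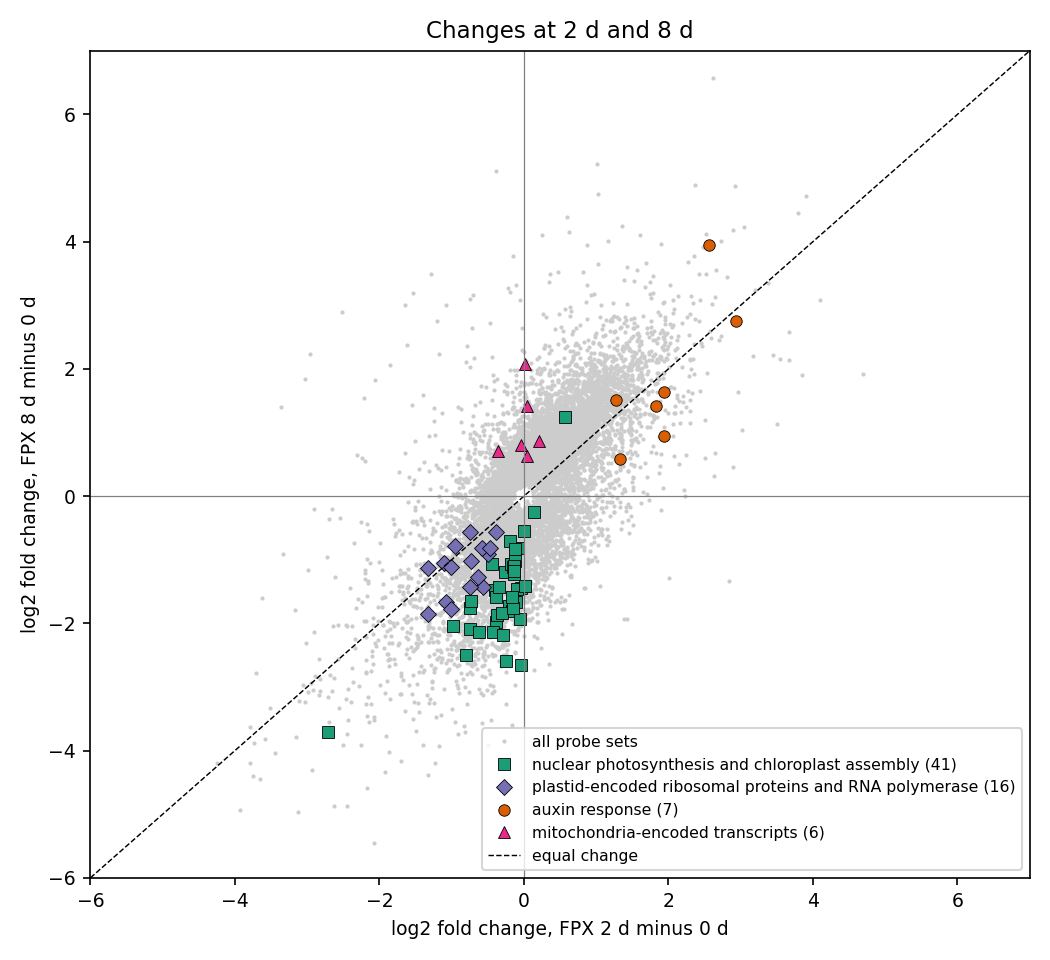
Log2 fold change at 8 d (vertical axis) against that at 2 d (horizontal axis), both against 0 d, with a grey point for each tested probe set, coloured markers for 4 gene groups and a dashed line of equal change. The 7 auxin response genes lie above 0 on both axes, and the 16 plastid-encoded ribosomal and polymerase transcripts below 0 on both.

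Few genes of the other lists were found by name in the table, where 5025 probe sets stayed unnamed. Of root meristem and callus regulators LHW and JKD were measured and rose, by 1.02 and 0.69 at 2 d and by 2.12 and 0.44 at 8 d, although JKD did not pass at 8 d after quantile normalization (0.12) or with array medians set to 0 (0.19). Of shoot meristem regulators PHV rose by 0.97 and 2.25, and YAB3 fell by 1.53 at 8 d. The auxin synthesis gene YUC2 changed by −0.66 at 2 d and −0.71 at 8 d, and the ribosome biogenesis gene AT5G14520 rose by 1.24 and 1.91. The ethylene signalling gene RTE1 rose by 1.51 at 8 d, and the lignin pathway gene HCT fell by 0.74. LTI30 changed by −1.24 at 2 d, and the other dehydrin gene of the water stress list, COR47, by −0.41 at 2 d and 0.82 at 8 d. The heat shock list held AT5G48570 (−2.09 and −2.17) and BOB1 (0.36 and 0.98, with 0.18 and no pass at 2 d with array medians set to 0), and the iron deficiency list PYE (−0.28 and −0.71) and AT3G13610 (−0.26 and −0.88). The falls of PYE and AT3G13610 at 2 d did not pass without 0 d replicate 1 or under the scaling on hybridization controls, and PYE was −0.17 without FPX 2 d replicate 3. Of glucosinolate genes the transporter gene GTR1 changed by −0.37 and −0.83, and BCAT4 rose by 0.77 at 8 d. Of flowering genes SMZ changed by −0.93 and −2.10, and GI rose by 0.62 at 8 d, which did not pass after quantile normalization. SAG101, of the salicylic acid list, changed by −0.33 at 2 d and 0.71 at 8 d. The falls of SAG101 and COR47 at 2 d did not pass without 0 d replicate 2. Of reference genes the tubulin gene TUB6 changed by −0.39 and −0.53, and GAPC2 by −0.33 at 8 d, which became 0.21 after quantile normalization and did not pass under the scaling on hybridization controls. At 2 d GAPC2 passed when adjusted over the list alone. The lists for cytokinin, jasmonate, phosphate starvation, root hair, endodermis, xylem and cuticle had 0 genes found by name in the selected table.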

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

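In this part, the tests of hybridization controls, of brightness and of background were chosen only after the results had been seen, and the counts over other splits of the arrays were planned before. Effects against 0 d that differed in direction between 2 d and 8 d, by the contrast of both times and by a call at each time, were seen at 283 probe sets that fell at 2 d and rose at 8 d, and at 392 that rose and then fell. Among the named genes, sks15 went from −2.22 at 2 d to 1.55 at 8 d (difference 3.76) and UGT73B4 from −0.80 to 2.11 (difference 2.91). GSTU26 went from −1.24 to 1.18 (2.42), OLEO3 from −0.58 to 0.86 (1.44), and GER2 from −0.57 to 1.03 (1.60). COR47 differed by 1.23 and SAG101 by 1.04 between the times, although their falls at 2 d did not pass when only the compared groups were fitted. SWEET2 rose at 2 d and then fell, with a difference of −2.11. Among the control probe sets, which were not among those tested, a plant actin probe set was higher on each 8 d array than on each 0 d array, by 0.178, and a bioC hybridization probe set by 0.264. Both went against the mean of their kind, and with 3 arrays against 3 the exact p cannot fall below 0.1.

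Other splits of the 6 arrays of each contrast number 10 with the real one, too few for a share under 0.05. In the contrast of 2 d with 0 d, 1 of the 10 splits, the real one, gave 8160 probe sets in limma, and the highest of the others gave 0 (152 at an unadjusted p under 0.05). For 8 d with 0 d the real split gave 10217 and the highest other 0 (59 unadjusted), again 1 of 10. For 8 d with 2 d the real split gave 8534 and the highest other 0 (123 unadjusted), also 1 of 10. For the F test, 1 of 100 splits of the 9 arrays, the real one, gave 11142 and the highest other 5871. The table was selected on the real split, so these counts do not say whether chance can be excluded.

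More probe sets rose than fell at 8 d against 0 d, with a median log2 change of 0.36, and 51.7% to 67.9% of calls were rises under other scalings, while at 2 d the direction of the split turned with array medians set to 0 (46.3% up). A higher background added equally to each probe set stays open. The signal added at 8 d was 1.97 times as large in the next dimmest 2807 probe sets as in the 2807 dimmest (131 against 66.3, 95% bootstrap interval 1.81 to 2.24). That test was run after the difference of 0.74 below was seen. Their 0 d medians were 301.6 and 136.1, and all had been selected for differing between the groups. Brighter probe sets may thus gain more signal whether or not background rose. The bootstrap resampled probe sets, so its interval does not measure the spread between arrays. Some other rise of dim signal on the treated arrays stays open too, since the median 8 d change was 0.56 in the 2807 dimmest probe sets and −0.18 in the 2807 brightest, a difference of 0.74 in the direction that such a rise may give. Scaling to a common level after the loss of bright transcripts also stays open, because the hybridization controls changed by −0.247 at 8 d, not upward, but were themselves selected for differing and number 3 arrays against 3. Treatment, age and a batch difference of the 0 d arrays were not tested as explanations of this pattern.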

How the results depend on the processing

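The scaling on hybridization controls and the adjustment as for 2 times as many tests were chosen after seeing the data, and the other alternatives were planned. Counts moved most where fewer units or a fold bound entered by construction. With the 5614 brightest probe sets alone, 4251 changed at 2 d (2288 up, 1963 down), 5141 at 8 d (2706 up, 2435 down), 4407 between 2 d and 8 d (2298 up, 2109 down) and 5579 in the F test. With a fold of at least 2 these were 1592 (1037 up, 555 down), 4167 (2407 up, 1760 down), 1989 (734 up, 1255 down) and 4502. With genes in place of probe sets they were 4255 (2668 up, 1587 down), 5443 (3395 up, 2048 down), 4484 (2698 up, 1786 down) and 5891. Leaving out each array in turn gave 7496 to 8197 at 2 d, 9969 to 10209 at 8 d, 7919 to 8586 between them and 10998 to 11055 in the F test. The correlation of the 2 d and 8 d changes was 0.673 after quantile normalization, 0.723 and 0.712 without the 2807 dimmest probe sets and with the 5614 brightest alone, and 0.707 to 0.721 without each array in turn, against 0.716. Adjusted as for 2 times as many tests, 4647 rose and 2884 fell at 2 d, and 6024 rose and 3936 fell at 8 d. Replicate numbers did not pair the samples (r of same-numbered deviations −0.091 to 0.106, over 0.1 in 1 of 9 pairs), and with the replicate number as a block 8115, 10191 and 8507 probe sets changed in the 3 contrasts and no call of a fixed list changed.

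For light harvesting at 2 d (camera adjusted p = 0.0328), the call ended after quantile normalization (0.793), with the 5614 brightest probe sets alone (0.0701) and under the scaling on hybridization controls (0.0535), and leaving out arrays gave 0.0168 to 0.0608. For the wall list at 2 d (0.00981) it ended without the 2807 dimmest probe sets (0.101) and with the 5614 brightest alone (0.332). At 8 d (0.0586) the wall list passed with genes in place of probe sets (0.0369) and under the scaling on hybridization controls (0.018), and leaving out arrays gave 0.0458 to 0.0645. For G2 and M phase at 8 d (0.0347) the call ended without the 2807 dimmest probe sets (0.0815). For flavonoids leaving out arrays gave 0.0498 to 0.0956 at 8 d and 0.0478 to 0.118 between 2 d and 8 d. For all of these the cause was not tested. Quantile normalization turned LHCB4.1 at 2 d from −0.26 to 0.0024, GAPC2 at 8 d from −0.33 to 0.21 and PYK10 at 8 d from −0.39 to 0.15, and the cause was not tested. The signal over background of dim probe sets is unknown here, which limits the calls that end without them.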

Other observations

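In this part, all tests of explanations were chosen after the results were seen. The group of mitochondria-encoded transcripts and the genes singled out were also chosen then. The signal of plastid-encoded transcripts fell. Whether their capture or labelling changed between the times was not tested, so a lower signal need not be a lower transcript level. The poly(A) controls, added before labelling, also fell, with a mean log2 change of −0.365 at 2 d and −0.568 at 8 d. Of 16 for ribosomal proteins and the plastid RNA polymerase 16 fell at 2 d (median −0.75, camera adjusted p = 7.22e-06, and 0.264 with an estimated correlation) and 16 at 8 d (median −1.09), with rpoB at −1.33 and −1.12 and rps2 at −1.01 and −1.77. Of 24 for the photosystems, cytochrome b6f and rubisco 12 fell (10 when adjusted over the list alone) and 1 rose (psbK) at 2 d, and 24 fell at 8 d (median −1.01), with rbcL at −0.80 and −1.66. Of 7 for the NADH dehydrogenase-like complex 6 and then 7 fell (medians −0.72 and −1.28), with ndhG at −1.07 and −2.76, and of 6 for ATP synthase 4 and then 6 fell, although atpE turned to 0.02 at 2 d after quantile normalization. Of 41 nuclear genes of photosynthesis and chloroplast assembly 17 fell (13 when adjusted over the list alone) and 1 rose at 2 d (median −0.18), and 40 fell and 1 rose at 8 d (median −1.58, adjusted p = 4.09e-13, and 0.193 with an estimated correlation). The gene that rose was TAAC (0.56 and 1.24), a thylakoid carrier. At 2 d the call of the nuclear group ended after quantile normalization (adjusted p = 0.0547), as did those of the photosystem (0.346) and NADH dehydrogenase-like (0.123) groups. The 28 groups gave 28 calls in 84 tests at the preset correlation and 0 with an estimated one.

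Most genes of the groups of transcription, RNA processing and DNA replication rose. Over all 11228 probe sets 5005 rose and 3155 fell at 2 d, and 6159 rose and 4058 fell at 8 d. Of 12 subunits of nuclear RNA polymerases 11 rose at 2 d (median 0.74) and 12 at 8 d (median 1.14, camera adjusted p = 0.00875, and 0.193 with an estimated correlation), with NRPA1 at 1.79 and 2.46. The call of the polymerase subunits ended at both times with the 5614 brightest probe sets alone (0.0733 and 0.0776). Of 27 genes of RNA processing and export 21 rose at 2 d and 26 at 8 d (median 0.83, adjusted p = 0.000569, and 0.193 with an estimated correlation), with the helicase gene PRH75 at 0.95 and 2.41. Of 20 genes of DNA replication and repair 17 rose and 1 fell at 2 d, and 19 rose and 1 fell at 8 d (median 1.21, adjusted p = 0.00365, and 0.193 with an estimated correlation). They included UNG (1.74 and 2.50), and DRT100 fell at both times (−1.39 and −1.82). Of 15 genes of mitosis and cytokinesis 12 rose at 2 d (SIM fell when adjusted over the list alone), and 14 rose and SIM fell at 8 d (adjusted p = 0.0359, with 0.225 at an estimated correlation and 0.0541 under the scaling on hybridization controls). The calls of the DNA replication and mitosis groups ended without the 2807 dimmest probe sets both at 2 d (0.172 and 0.092) and at 8 d (0.128 and 0.121). With the 5614 brightest alone the values were 0.723 and 0.186 at 2 d and 0.731 and 0.186 at 8 d. Of 7 RALF-like peptides and their receptor kinases 5 fell at 2 d, and 6 fell and RALFL31 rose (0.42) at 8 d (median −1.25, adjusted p = 0.0174, and 0.212 with an estimated correlation), with RALFL22 at −1.10 and −1.63 and THE1 at −0.83 and −1.25. Of 24 UDP-glycosyltransferase genes 14 fell and 4 rose at 2 d, and 14 fell and 7 rose at 8 d. ATGSTF13, a glutathione transferase gene chosen after its values were seen, went from −1.14 at 2 d to 1.31 at 8 d. The 6 mitochondria-encoded transcripts, which are those the annotation names, had a median of 0.02 at 2 d that turned to −0.20 after quantile normalization, and 6 of 6 rose at 8 d (median 0.84, adjusted p = 0.12), with ccb452 at 2.08, nad1 at 1.41 and cox1 at 0.72. At 2 d cox1 had fallen, by −0.36 (limma adjusted p = 0.0337).

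Plastid-encoded ribosomal and polymerase transcripts had most of their 8 d fall by 2 d (median 70.3%), and photosynthesis transcripts less of it (20%, from −52.7 to 73.2%, in the 77 probe sets called fallen at 8 d, which leaves out TAAC), with 13.3% in nuclear genes, 27.2% in plastid-encoded photosystem, 33.2% in ATP synthase and 38.7% in NADH dehydrogenase-like transcripts. Saturated signal of the brightest photosynthesis probe sets is argued against as the whole cause, for nuclear and plastid-encoded ones pooled. The 60 of these that were no brighter at 0 d than the brightest ribosomal or polymerase probe set had a median of 19.9% (permutation p = 1e-05, the smallest that 100000 resamples can give). The 60 shared only an upper bound of 8900.7 with the ribosomal and polymerase probe sets and were not matched to them in brightness. Of the 77 probe sets 40 were nuclear, and saturation of the plastid-encoded ones was not tested alone. An equal loss of plastids or of plastid RNA would lower all plastid-encoded transcripts alike. At 2 d the median of the plastid-encoded photosystem transcripts lay above that of the ribosomal and polymerase ones by 0.53 (permutation p = 0.00054). For all 37 photosynthesis transcripts the difference was 0.49 (permutation p = 0.00047). These differences are part of the pattern that prompted the test. They argue against equal loss as the whole cause for photosystem transcripts only if saturation and capture were alike in both groups, which was untested. The permutations shuffled transcripts, which are not independent replicates, so their p-values do not measure the spread between arrays. An equal loss stays open for the NADH dehydrogenase-like (difference 0.03, permutation p = 0.77) and ATP synthase transcripts (0.37, permutation p = 0.057). At 8 d the medians of all 37 and of the 16 were −1.21 and −1.09 (permutation p = 0.65). Age of the seedlings in place of the compound cannot be told apart from treatment. There were 0 arrays of untreated seedlings of the later ages. A batch difference of the 0 d arrays and a change in the capture or labelling of plastid-encoded transcripts were not tested.

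Mitochondria-encoded transcripts rose at 8 d while plastid-encoded ones fell. Scaling of the arrays is argued against as the whole cause of the rise, since the lowest mitochondrial median over 3 other scalings was 0.58. A change in the capture or labelling of organelle transcripts stays open, because the difference of 1.96 between the 8 d medians of 6 mitochondrial (0.84) and 53 plastid transcripts (−1.12) is the pattern itself and excludes nothing. Signal from nuclear copies of mitochondrial genes was not examined. Treatment, age and a batch difference of the 0 d arrays were not tested as explanations of this pattern.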
